A study of Homo sapiens with 3 samples.

How the data were processed

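C4-2B prostate cancer cells were treated with vehicle or with Ilicicolin A (IliA) at 5 or 10 µM for 48 h, and 1 RNA-seq library per condition was analysed, 3 in all. Per the labels' protocols, libraries were made from 1 µg of total RNA and sequenced as single-end reads of 50 bases. Each library was assigned to its group by its title, since the agent tag is the same on all 3 samples, the vehicle library included. That tag reads Ilicicolinal A, whereas the series title reads Ilicicolin A, and the name in the series title is used here. In addition, the sources used here do not say whether the cultures were handled on the same day. The deposited values are FPKM computed by the authors, that is, fragments scaled to gene length and library size; with single-end reads this is the same quantity as RPKM. Per the submitters' processing notes, the tools were Trim Galore, BWA, Bowtie2, Cufflinks and Cuffdiff and the genome build was hg19. The versions, the role of each tool, the annotation and the use of strand are not given in the sources used here. FPKM sets each library to the same sequencing depth, so a shift in total RNA per cell is not visible, and reads of near-identical genes can be divided between copies.

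The 3 libraries list the same 11549 names in the same order, and the lowest value is 1 FPKM in each, so only genes at 1 FPKM or more in all 3 libraries were analysed. Genes silent in the vehicle library or in a treated library are therefore outside every count. Symbols of 20 genes had been turned into dates and 9 names were numbers, and 2 entries shared a name; they were kept in the counts and none is named. Read depth is unknown. Among 20 genes with a transcript under 700 bases and under 6 FPKM, values given to 2 decimals showed no steps of whole reads, so no counting intervals could be given. The spread between the treated libraries stands in for precision: 95% of log2 ratios of 10 µM over 5 µM lay between −0.34 and 0.35 among the least expressed of 4 groups of genes and between −0.25 and 0.20 among the most expressed.

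From the FPKM, log2 ratios of FPKM + 1 were computed for 5 µM over vehicle, 10 µM over vehicle and 10 µM over 5 µM. A minimum mean of 1 FPKM was set and removed 0 genes. With 1 library per group no test was run, and genes at least 2-fold apart were counted. The design, the alternatives and 38 gene lists were fixed before the data were examined. For each list with 3 or more members analysed, 35 in all, the median log2 ratio was set against 10000 random lists of the same size drawn from 20 bins of mean expression. A percentile under 2.5 or over 97.5 is called outside the central range, which takes in 5% of random lists. Intervals of the median are 95% order-statistic intervals over genes and describe these libraries only. They were given from 6 members on. Lists share members in places, such as CDKN1A, BIRC3, NDRG1, RRM2 and SLC7A11.

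The genes named are EZH2, EED, SUZ12, EZH1 and KLK3, and for each dose against vehicle the 10 highest and 10 lowest genes, without short or unnamed RNAs. For 10 µM against 5 µM they are the 5 highest and 5 lowest. Of each list, up to 4 members past 2-fold at 10 µM were named, or up to 2 where none passed, with every marker of another cell type. Because both doses share the vehicle library, unchanged groups were simulated in 100 draws, with the error taken from the spread between the treated libraries, and expected overlaps of independent lists were computed. Alternatives were pseudocounts of 0.1 and 5, no minimum and a minimum mean of 5 FPKM, thresholds of 1.5-fold and 3-fold, rescaling to the same total or by the median ratio, lists without their most changed member and random lists not matched on expression. Removal of the trend with transcript GC content, transcript length and gene span was added after the data were seen. These properties came from the longest annotated transcript and the RefSeq span on a newer genome build and were found for 98.5% of genes. No coordinates are given because of the difference in build. Another 7 lists were chosen after the data were seen and stand under the other observations. A few genes the rule named and 2 of the 38 lists are not reported here, although the counts of genes and lists include them.

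The calculations were tested on simulated data. Of 50 genes per fold simulated for 10 µM against vehicle among 11549, the share called past 2-fold was 0% at a true fold of 1.5, 24% at 2, 96% at 3 and 100% at 4, and 0 of 11349 unchanged genes were called. Of 100 unchanged lists, 2 fell outside the central range, and 20 of 20 lists of 30 genes shifted by 0.3 were found. The error of each simulated library, the vehicle included, came from the spread between the treated libraries and was independent between genes. These figures are therefore no error rates for the real comparisons with vehicle. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.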

Results

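RNA-seq was carried out on C4-2B cells, a castration-resistant and bone-metastatic derivative of the LNCaP prostate cancer line, after 48 h in vehicle or in Ilicicolin A (IliA), a fungal metabolite, at 5 µM or 10 µM. The title of the series names EZH2, the histone H3 methyltransferase of Polycomb repressive complex 2 (PRC2), so the comparisons ask how EZH2, its targets and the rest of the transcriptome stood at each dose. Each of the 3 groups was 1 library, so no difference given here has a replicate check and no p-value was computed. Values are FPKM for 11549 genes, each at 1 FPKM or more in all 3 libraries. Listed values summed to 494404 FPKM in the vehicle library, 497697 FPKM at 5 µM and 490974 FPKM at 10 µM, with medians of 12.8, 13.0 and 13.0 FPKM. Read depth is unknown. Differences are log2 ratios of FPKM + 1, on which 1 stands for 2-fold and which understate the ratio of low genes.

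Against vehicle, EZH2 mRNA was lower at both doses, but by less than 2-fold. It stood at 20.3 FPKM with vehicle, 14.7 FPKM at 5 µM and 15.1 FPKM at 10 µM, log2 ratios of −0.44 and −0.40. Among the 577 genes of like expression, these ratios lay at percentiles 9.71 and 10.4. Of its partners in PRC2, EED was higher, with log2 ratios of 0.27 at 5 µM and 0.44 at 10 µM, and SUZ12 was lower, with −0.24 and −0.15. EZH1, the other catalytic subunit, had log2 ratios of 0.06 and 0.23. The 12 PRC2 subunits as a list showed no common direction, with none past 2-fold and medians of 0.0050 (95% interval −0.24 to 0.17) at 5 µM and −0.0089 (−0.21 to 0.18) at 10 µM. The first of these medians was −0.023 after rescaling by the median ratio. Among 20 H3K27 demethylases and PRC1 subunits, none passed 2-fold and the medians were −0.12 and −0.02, at percentiles 5.11 and 26.1. Without the trend across GC content, transcript length and gene span they were −0.17, at percentile 0.990 and so below the central range, and −0.087, at percentile 8.02. KDM6A, an H3K27 demethylase, was at 42.5 FPKM with vehicle and at 26.7 and 27 FPKM in the treated libraries. The log2 ratios of BMI1, a PRC1 component, were −0.35 and −0.55.

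Of 28 genes described as silenced by EZH2 in cancer cells, 12 were analysed, and 11 of these were above vehicle at each dose. Only genes at 1 FPKM or more in all 3 libraries could enter. A rise of targets that were silent with vehicle could therefore not be seen here. The list median was 0.19 (0.05 to 0.53) at 5 µM and 0.26 (0.14 to 0.66) at 10 µM. Set against 10000 random lists of the same size and expression, the medians lay at percentiles 92.0 and 97.0, inside the central 95%. Past 2-fold, 2 members were higher at each dose and none was lower. Of these, CDKN1C, a CDK inhibitor, went from 1.84 FPKM with vehicle to 5.00 and 5.23 FPKM. Without members under a mean of 5 FPKM, 7 members were left and the median stood at percentile 98.9 at 5 µM, above the central range, and at 94.3 at 10 µM. With the trend across GC content, transcript length and gene span removed, the medians were 0.14 at 5 µM and 0.15 at 10 µM, at percentiles 85.3 and 87.6.

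KLK3, which encodes prostate-specific antigen, was lower with IliA, and MAF, NDRG1 and FKBP5 were more than 2-fold higher at both doses. KLK3 was at 1233 FPKM with vehicle, 1038 FPKM at 5 µM and 819 FPKM at 10 µM, log2 ratios of −0.25 and −0.59. Among genes of like expression these ratios lay at percentiles 27.3 and 8.30. The transcription factor MAF was at 1.38 FPKM with vehicle and at 11.97 and 7.18 FPKM with IliA. NDRG1 was at 31.1, 139 and 91.6 FPKM, and the co-chaperone FKBP5 at 53.7, 181 and 144 FPKM. HOXB13, a homeobox factor of the prostate, had log2 ratios of −0.29 and −0.59.

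**Figure D1:**
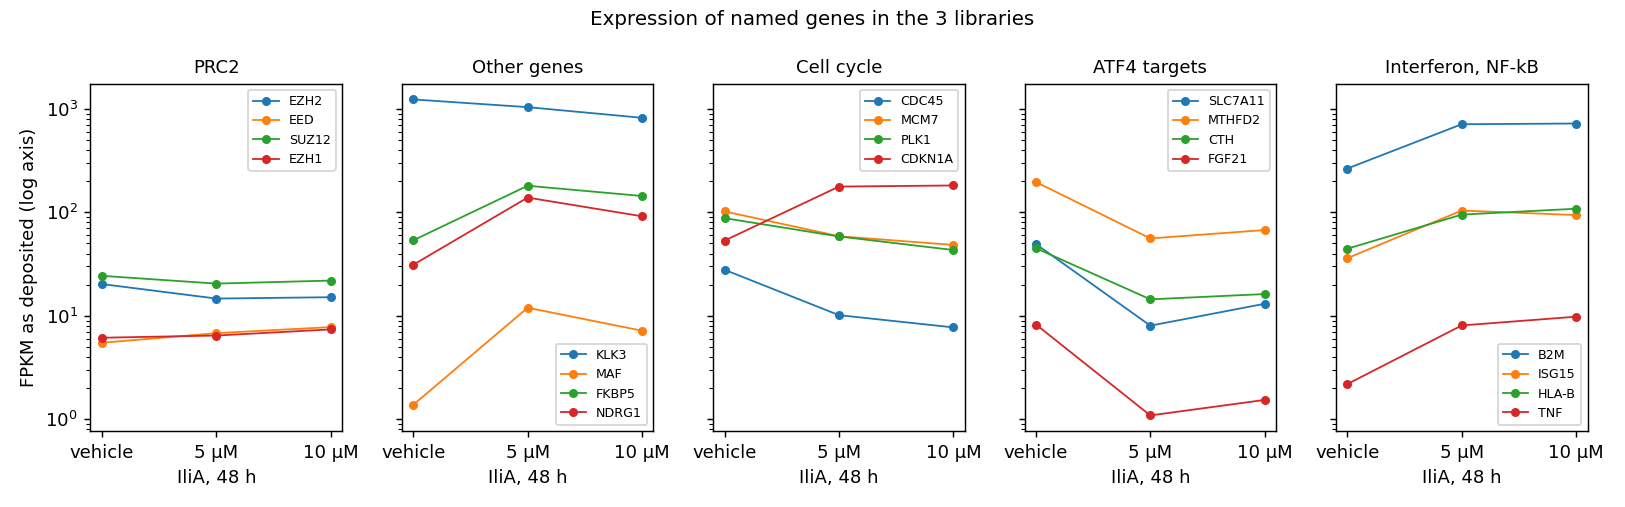
FPKM (log axis) of named genes in the 3 libraries, vehicle, 5 µM and 10 µM IliA, 1 library per group and so without error bars. EZH2 goes from 20.3 FPKM with vehicle to 14.7 and 15.1 FPKM, KLK3 is lowest at 10 µM, and SLC7A11, MTHFD2, CTH and FGF21 are lower and B2M, ISG15, HLA-B and TNF higher in both treated libraries.

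DNA replication and mitosis genes were lower at both doses and lower still at 10 µM. The replication-dependent histone genes, described below, had medians above vehicle instead. The 52 DNA replication and G1/S genes had a median log2 ratio of −0.39 (−0.52 to −0.28) at 5 µM and −0.52 (−0.69 to −0.36) at 10 µM, with 45 and 48 members below vehicle. The 59 G2/M and mitosis genes had medians of −0.49 (−0.56 to −0.42) and −0.62 (−0.72 to −0.56), with 56 and 57 members below vehicle. All 4 medians were lower than those of all 10000 random lists. Few members passed 2-fold. CDC45, part of the replicative helicase, was at 27.8 FPKM with vehicle, 10.2 FPKM at 5 µM and 7.73 FPKM at 10 µM. CDC6, RRM2 and MCM7 were past 2-fold at 10 µM, with log2 ratios of −1.13, −1.09 and −1.06. EXO1, picked after its values were seen, was 2-fold lower at both doses, with −1.03 at 5 µM. Of the 59 genes in the G2/M and mitosis list only PLK1 passed 2-fold, at 10 µM, with 87.9 FPKM with vehicle, 58.4 FPKM at 5 µM and 43.2 FPKM at 10 µM. Its log2 ratio of −1.01 came to −0.997, just short of 2-fold, after rescaling to the same total. The 27 homologous recombination and checkpoint genes had medians of −0.54 (−0.63 to −0.36) and −0.53 (−0.77 to −0.38), again lower than all random lists. BRCA1 had log2 ratios of −1.06 and −0.998 and FANCI −0.76 and −0.97.

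The p53 target genes were higher, with medians of 0.43 (0.06 to 0.64) and 0.38 (0.09 to 0.71) over 29 members, above all random lists. Of the members, 3 passed 2-fold at each dose, all higher, and 6 and 7 lay below vehicle. Of 4 members picked after their values were seen, MDM2 stayed level, at 16.5, 16.8 and 16.6 FPKM, and GDF15 (−0.76 and −0.63), SESN2 (−0.75 and −0.57) and PMAIP1 (−0.67 and −0.58) were lower. CDKN1A, which encodes the CDK inhibitor p21, was at 53.4 FPKM with vehicle, 177 FPKM at 5 µM and 182 FPKM at 10 µM. TP53I3 had log2 ratios of 1.72 and 1.39, and PLK2 of 1.31 and 1.25. The list of CDK inhibitors and G0 genes also takes in cyclins and CDKs, so its median does not describe the inhibitors alone. Its 15 members analysed had medians of 0.11 and 0.07, inside the central range, with CDKN1A and CDKN1C past 2-fold. Without the member with the largest change, the second was 0.016. The 31 apoptosis regulators had medians of 0.20 at both doses, at percentiles 98.4 and 98.8, with BIRC3 and, at 10 µM, BMF past 2-fold. BIRC3 encodes an inhibitor of apoptosis and BMF a pro-apoptotic protein. With members under a mean of 5 FPKM left out, the apoptosis list lay at percentiles 91.9 and 93.0, inside the central range.

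Genes of the amino acid response and of translation were lower in both treated libraries. ATF4 target genes, which supply amino acids and charged tRNAs, had a median log2 ratio of −0.73 (−0.83 to −0.45) at 5 µM and −0.54 (−0.65 to −0.34) at 10 µM, and 40 and 39 of 43 members lay below vehicle. Past 2-fold, 12 and 8 members were lower. SLC7A11, the cystine transporter subunit, was at 49.4 FPKM with vehicle, 8.03 FPKM at 5 µM and 13.1 FPKM at 10 µM. MTHFD2, a mitochondrial folate enzyme, was at 196, 56.0 and 67.4 FPKM. The secreted hormone FGF21 was at 8.24, 1.09 and 1.54 FPKM, and CTH, which makes cysteine, at 45.0, 14.4 and 16.2 FPKM. The 25 genes of the unfolded protein response had medians of −0.45 (−0.53 to −0.37) and −0.47 (−0.64 to −0.39), with 24 and 25 members below vehicle and none past 2-fold. The ER chaperone HYOU1 had log2 ratios of −0.89 and −0.92, and HERPUD1 of −0.68 and −0.84. Of 74 cytosolic ribosomal proteins, 71 lay below vehicle at 5 µM and 70 at 10 µM, with medians of −0.41 (−0.44 to −0.36) and −0.40 (−0.44 to −0.35). RPL23 was their only member past 2-fold, at 1915 FPKM with vehicle and 757 and 854 FPKM with IliA. The 35 genes of MYC and its ribosome biogenesis targets had medians of −0.22 (−0.32 to −0.10) and −0.29 (−0.37 to −0.08). Of these, NPM1 had log2 ratios of −0.94 and −0.88 and GNL3 of −0.84 and −0.73. The 24 pyrimidine and purine synthesis genes had medians of −0.31 (−0.48 to −0.14) and −0.32 (−0.64 to −0.18). At each dose the medians of these 5 lists lay at percentiles between 0 and 0.01.

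Interferon, antigen presentation and NF-kB genes were higher in both treated libraries. The 24 interferon and antigen presentation genes analysed, of 35, had medians of 0.70 (0.28 to 0.99) at 5 µM and 0.78 (0.20 to 1.08) at 10 µM, with 6 and 8 past 2-fold, all higher. B2M, the light chain of MHC class I, was at 265 FPKM with vehicle, 710 FPKM at 5 µM and 722 FPKM at 10 µM. ISG15 was at 36.0, 104 and 94.1 FPKM, IFI44 at 1.03, 3.54 and 3.96 FPKM, and HLA-B, whose reads can be shared with other class I genes, at 44.5, 95.04 and 108 FPKM. The 15 NF-kB and inflammatory genes had medians of 0.71 (0.55 to 1.12) and 0.90 (0.69 to 1.08), with 5 and 4 past 2-fold. TNF was at 2.19, 8.07 and 9.81 FPKM. The log2 ratios were 1.18 and 1.13 for CEBPD, 1.07 and 1.08 for TNFAIP3, and 1.12 and 1.31 for BIRC3. CCL2, picked after its values were seen, was at 1.09, 3.81 and 3.07 FPKM. The medians of both lists were above those of all random lists. The 14 immediate early genes had medians of 0.45 (−0.12 to 1.00) and 0.42 (−0.17 to 0.92), at percentiles 99.99 and 99.97, and JUNB had log2 ratios of 1.59 and 1.63 and JUND of 1.00 and 1.23.

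Markers of other cell types moved with these genes in part. The leukocyte markers analysed were CD68 (4.99, 27.3 and 27.9 FPKM at vehicle, 5 µM and 10 µM), LYZ (1.69, 7.61 and 4.53 FPKM) and CD8A (2.25, 1.65 and 1.35 FPKM), and their median log2 ratio was 1.68 and 1.04. Of the fibroblast markers, ACTA2 had log2 ratios of 0.83 and 0.78, TAGLN of 0.92 and 0.70, and COL1A1 of −0.23 and 0.13. The median of these 3 was 0.83 and 0.70, at percentiles 99.5 and 98.2. Of the basal markers ITGA6 was analysed, with −0.45 and −0.27, and no endothelial marker was analysed here.

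Of the metabolic and stress lists, lysosomal and lipid synthesis genes were higher at both doses and antioxidant genes at 10 µM. The 32 NRF2 target and antioxidant genes had a median of 0.13 (−0.06 to 0.50) at 5 µM, at percentile 84.1, and 0.37 (0.07 to 0.71) at 10 µM, above all random lists, with 11 and 8 members below vehicle. SLC7A11, also an ATF4 target, changed most of these, with log2 ratios of −2.48 and −1.84. Ferritin light chain FTL was at 448 FPKM with vehicle and 1160 and 1193 FPKM with IliA, the heme oxygenase HMOX1 at 52.9, 77.1 and 109 FPKM. The steroid reductase AKR1C3, which has near-identical paralogs, was at 2.59, 6.32 and 7.66 FPKM. The log2 ratio of HMOX1 at 10 µM was 1.03, and 0.996 after rescaling by the median ratio. The 30 autophagy and lysosome genes had medians of 0.24 (0.02 to 0.36) and 0.25 (0.12 to 0.39), at percentiles 99.6 and 99.8. Among them GPNMB was at 12.7, 58.5 and 61.0 FPKM, the sialidase NEU1 at 23.2, 73.9 and 67.5 FPKM and the autophagy receptor SQSTM1 at 384, 737 and 815 FPKM. The 21 fatty acid and lipid synthesis genes had medians of 0.29 (0.0043 to 0.60) and 0.33 (0.11 to 0.50), at percentiles 99.2 and 99.9, with ACSL1 past 2-fold at 10 µM, at 1.05. The 24 cholesterol synthesis genes had medians of 0.24 and 0.18, at percentiles 98.6 and 96.3, with none past 2-fold and TM7SF2 (0.85 and 0.87) and INSIG1 (0.69 and 0.84) farthest above vehicle. With the trend across GC content, transcript length and gene span removed, the cholesterol medians were 0.15 and 0.11, at percentiles 93.3 and 87.3.

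The remaining lists with a median inside the central range at both doses were as follows. The 20 cytosolic heat shock genes had medians of 0.21 and 0.16, with HSPB8 at 0.93 and 1.14, and the 17 PPAR target genes 0.17 and 0.20, with ACAA2 at 1.02 and 0.72. With a mean of at least 5 FPKM the PPAR median at 10 µM was 0.077. The 21 hypoxia response genes had 0.06 and 0.14, with CA12 at 0.86 and 1.11, and the hypoxia median at 5 µM was 0.12 with the trend removed and 0.031 after rescaling by the median ratio. The 67 nuclear-encoded respiratory chain genes had 0.12 (0.09 to 0.24) and 0.02 (−0.02 to 0.10), the second being −0.01 after rescaling by the median ratio. NDUFA2 was at 0.86 and 0.64, and NDUFB2 at 0.72 and 0.59. The 23 glycolysis genes had 0.05 (−0.08 to 0.29) and 0.0021 (−0.09 to 0.21), both below 0 once the trend was removed, with ALDOC at 1.31 and 1.30 and the monocarboxylate transporter SLC16A3 at 1.29 and 1.05. The 14 epithelial and mesenchymal genes had 0.11 and 0.14, or 0.052 and 0.062 with the trend removed, and held members far apart. The mesenchymal transcription factor SNAI2 was at 2.73, 18.2 and 13.8 FPKM and the epithelial splicing regulator ESRP1 at 77.4, 33.4 and 36.4 FPKM. The 11 luminal markers had 0.26 (−0.60 to 0.81) and 0.10 (−0.63 to 0.70), with 6 above and 5 below vehicle and KRT8 at 1.26 and 1.07. Without the member with the largest change, the luminal medians were 0.0061 and −0.032. The 3 neuroendocrine markers analysed had 0.09 and 0.19, with ENO2 at 0.76 and 0.87 and ONECUT2 at 0.09 and 0.19, and their median at 5 µM was 0.23 with the trend removed. No mitochondrially encoded gene was analysed here. Outside the central range, 5 metallothionein genes and regulators had medians of −0.54 and −0.39, at percentiles 0.42 and 1.75, with the zinc exporter SLC30A1 above vehicle at 0.92 and 1.02. Rescaled by the median ratio, ACAA2 at 5 µM and SLC30A1 at 10 µM were just short of 2-fold, at 0.996 and 0.98. The 12 replication-dependent histone genes had 0.60 (−0.36 to 0.86) and 0.67 (−0.37 to 0.90), above all random lists. At each dose 9 of them lay above vehicle and 3 below, unlike the replication and mitosis lists. HIST2H2BE was at 27.9, 97.9 and 90.7 FPKM, HIST2H2AA3 at 35.5, 87.6 and 82.9 FPKM and HIST1H2BJ at 5.91, 2.73 and 1.69 FPKM, and near-identical histone copies can share reads.

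**Figure D2:**
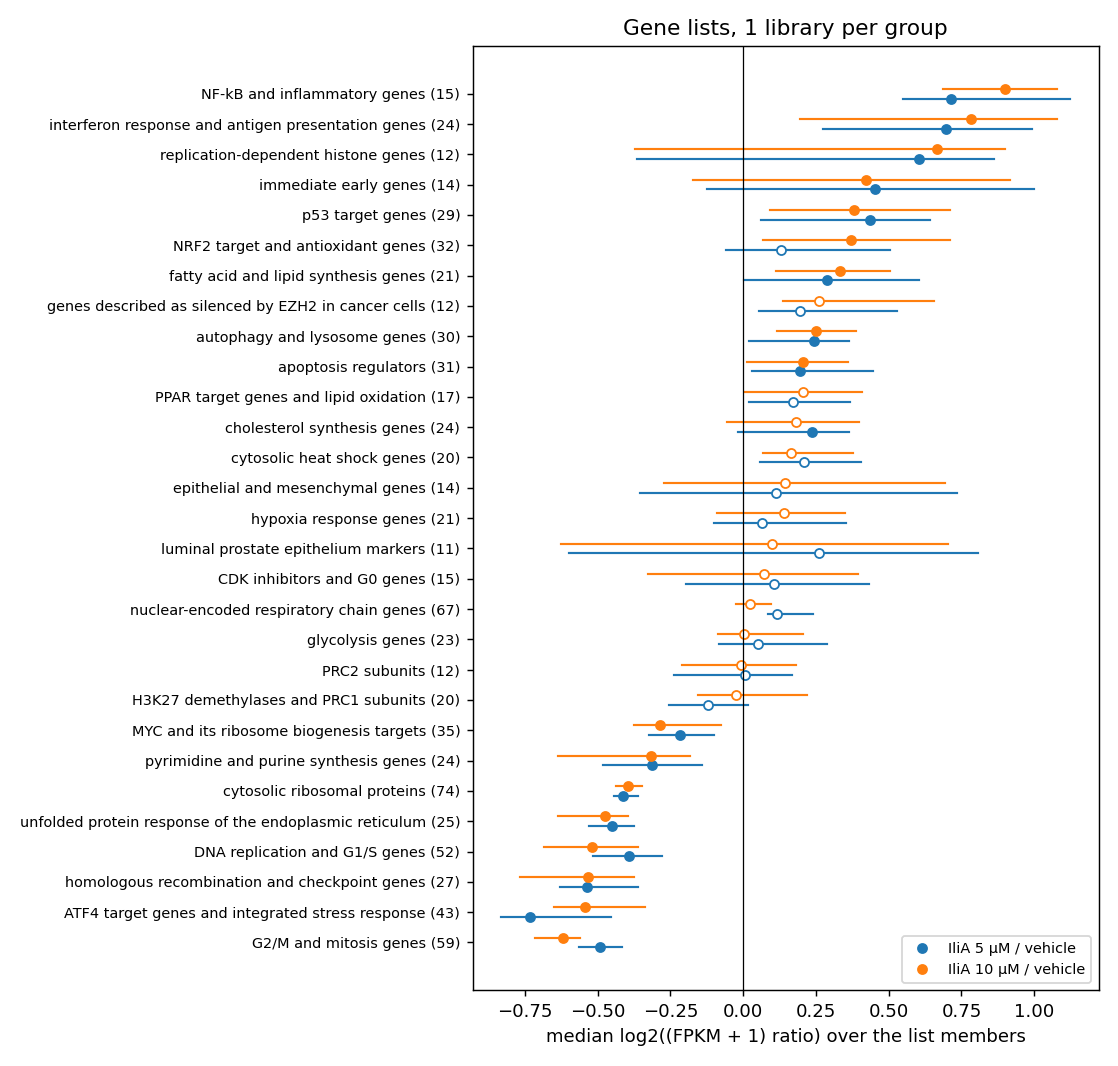
Median log2 ratio of FPKM + 1 over the members of each gene list with 6 or more genes analysed, for 5 µM (blue) and 10 µM (orange) IliA against the same vehicle library, 1 library per group. Lines are 95% order-statistic intervals of the median over genes, the number of genes stands in parentheses, and filled points lie outside the central 95% of 10000 expression-matched random lists. NF-kB genes have medians of 0.71 and 0.90, and G2/M genes −0.49 and −0.62.

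Across all 11549 genes, 221 were at least 2-fold higher and 98 at least 2-fold lower at 5 µM than with vehicle, and 208 and 93 at 10 µM. The genes farthest above vehicle encoded secreted proteins in several cases. SAA1, an acute phase protein, was at 2.46 FPKM with vehicle, 61.4 FPKM at 5 µM and 60.0 FPKM at 10 µM. PIP was at 4.24, 94.6 and 75.6 FPKM, the elastase inhibitor PI3 at 5.12, 53.5 and 48.2 FPKM, and APOD at 3.42, 26.1 and 19.6 FPKM. CYP1A1, a P450 that metabolises xenobiotics, was at 2.94, 21.7 and 31.1 FPKM. NPPC, NBL1 and MICAL1 also stood among the 10 highest at 5 µM, with log2 ratios of 2.59, 2.41 and 2.31, and IL32 and NOS3 among the 10 highest at 10 µM, with 2.22 and 2.07. Of the lowest genes, CAMK2N1, an inhibitor of CaM kinase II, was at 68.8, 13.4 and 12.7 FPKM, CYB5D2 at 25.3, 4.92 and 4.30 FPKM, and the cation transporter SLC22A3 at 7.86, 1.38 and 1.02 FPKM. The adhesion molecule NCAM2 was at 65.2, 17.9 and 15.5 FPKM. The condensin subunit SMC4 had log2 ratios of −1.77 and −1.85, the spindle gene SKA2 of −1.53 and −1.78, and ANK3 of −1.66 and −1.70. FAM72C, at −2.13 and −1.70, and EIF3C, at −1.87 and −1.56, have near-identical copies and are uncertain. Of 35 lists with a median, 12 lay above and 9 below the central 95% of random lists at each dose, where 1.75 on either side together would be expected of random lists. With the trend removed, 11 lay above and 10 below at 5 µM, and 12 and 9 at 10 µM. The 1.75 holds for lists of unrelated genes, whereas members of these lists can move together, so it is no measure of chance here. Between the treated libraries, 10 lists lay above and 5 below. Both comparisons share a trend with base composition: across genes, Spearman's rho of the log2 ratio with transcript GC content was 0.325 at 5 µM and 0.290 at 10 µM.

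At 10 µM against 5 µM, the libraries were close, and the differences lay in whole lists more than in single genes. LAMP3, a lysosomal membrane protein, was 2-fold higher (3.27 and 7.70 FPKM at 5 and 10 µM, 15.1 FPKM with vehicle) and NPIPA1, from a multi-copy family, 2-fold lower (6.36 and 2.59 FPKM). No other gene passed 2-fold, and 95% of log2 ratios lay between −0.28 and 0.27, against −0.75 to 0.91 for 5 µM over vehicle. G2/M genes were lower at 10 µM than at 5 µM in 57 of 59 cases (median −0.18, −0.20 to −0.13) and G1/S genes in 44 of 52 (−0.13, −0.16 to −0.08). Respiratory chain genes were lower in 62 of 67 (−0.10, −0.12 to −0.08). All 3 medians lay below those of all random lists. With the trend removed, the respiratory chain median was −0.059, at percentile 0.05, and those of G2/M and G1/S genes were −0.16 and −0.11, still below all random lists. This comparison has a trend of its own, with a rho of 0.260 between its log2 ratio and transcript length, 0.187 with gene span and −0.107 with GC content. ATF4 targets were higher in 39 of 43 (0.16, 0.14 to 0.19) and NRF2 targets in 24 of 32 (0.17, 0.03 to 0.27), above all random lists. Of 35 lists, 10 lay above and 5 below the central range, and 10 and 8 with the trend removed. The number above depends on matching: of 33 lists recomputed, 10 lay above and 4 below matched random lists, and 5 and 6 when the random lists were not matched on expression. Among the 5 genes farthest in each direction, FAM72D, SERF1A and the read-through ATP5MF-PTCD1 were lower, with −0.95, −0.89 and −0.88, and TBC1D3E, MAGEA2B and PRSS1 higher, with 0.76, 0.78 and 0.80. These 6 share sequence with other genes and are uncertain. LGALS1, at −0.87, and MOV10L1, at 0.76, were under 5 FPKM in all 3 libraries.

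**Figure D3:**
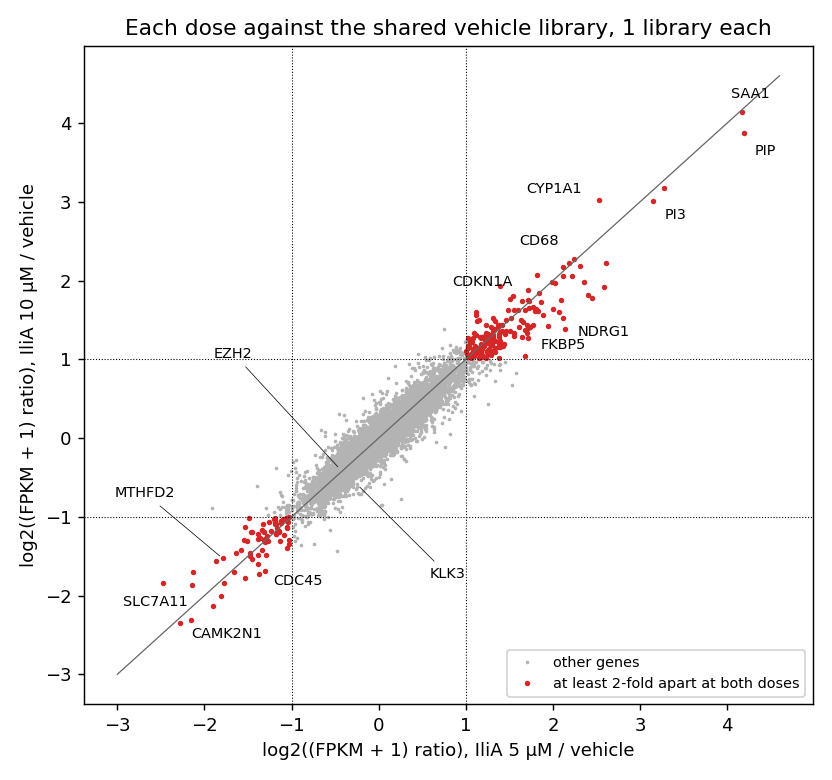
Log2 ratio of FPKM + 1 at 5 µM (x axis) and 10 µM (y axis) over the same vehicle library, 1 point per gene, 1 library per group. Red points are the genes at least 2-fold apart from vehicle in the same direction at both doses, 167 higher and 70 lower; dotted lines mark 2-fold and the solid line equal ratios.

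Genes past 2-fold at the 2 doses overlapped. Of the genes higher at either dose, 262 in all, 167 were higher at both, and of 121 lower at either, 70 were lower at both; none was past 2-fold in opposite directions. Independent lists of these sizes would share 3.98 and 0.789 genes, and in simulated unchanged groups against the shared vehicle no gene passed 2-fold, so their overlap of 0 was fixed in advance and is no measure of chance. Across genes, which are not independent replicates, Pearson's r between the log2 ratios was 0.942 and Spearman's rho 0.929, and unchanged groups sharing the vehicle library gave r of 0.501. The covariance was 0.162 against a simulated 0.00974, a difference of 0.152. The sign was the same for 88.6% of genes, against 66.7% in the simulation. The simulation took the vehicle library to vary as much as the treated libraries vary from each other, which a single vehicle library cannot show. Part or all of the excess, and of the overlap, may therefore come from the shared vehicle.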

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

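Several results had opposite signs at the 2 doses against the same vehicle library. With 1 library per group the differences between doses were not tested, and no group was large enough to search for a library far from the others. The median over PRC2 subunits was 0.0050 at 5 µM and −0.0089 at 10 µM, both inside the interval of the other. NPIPA1, a member of a multi-copy family, was at a log2 ratio of 0.26 at 5 µM and −0.77 at 10 µM. SERF1A, which has a near-identical copy, was at 0.043 and −0.85, and the read-through gene ATP5MF-PTCD1 at 0.029 and −0.85. LGALS1, which encodes galectin-1, was at 0.76 and −0.11. In the other direction, MOV10L1 was at −0.66 and 0.10, TBC1D3E at −0.45 and 0.31, and the collagen gene COL1A1 at −0.23 and 0.13. The single genes named here were all under 7 FPKM in each library, where ratios between the treated libraries spread most.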

How the results depend on the processing

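The trend removal was chosen after seeing the data; the other settings were planned. No list outside the central range and no named gene past 2-fold turned its direction under any setting run for it, in the 3 comparisons. The counts depended on the pseudocount and the threshold. Counts are given as higher and lower at 5 µM, at 10 µM and at 10 over 5 µM, then higher and lower at both doses. A pseudocount of 0.1 gave 337 and 148, 327 and 160, 3 and 5, and 253 higher at both. A pseudocount of 5, which shrinks low genes, gave 106 and 42, 87 and 34, 0 and 0, and 73 and 29. A 1.5-fold threshold gave 886 and 614, 857 and 615, 21 and 23, and 677 and 457, and a 3-fold threshold 51 and 13, 41 and 13, 0 and 0, and 35 and 9. With a mean of at least 5 FPKM, 0 genes were lower at 10 over 5 µM. All other counts, 40 in number, stayed within 1.5 times. Having no minimum removed nothing and tests nothing. Its values equal the main ones by construction, yet 8 of those 40 counts and 99 of the list medians tallied next come from it. Of 168 medians of the lists behind the main comparisons, 159 kept their place inside or outside the central range and lay within the 95% interval of the main median, where 1 was given. That interval is wide, so 1.5 times and the sign were counted as well: among medians inside the central range, 12 of these lists' values moved by over 1.5 times with the same sign and 3 more changed sign, and 41 and 12 of the other lists' values did. Among those outside it, none did and all stayed within 1.5 times but the cholesterol median at 5 µM without the trend and, at 10 over 5 µM, the ribosomal and respiratory chain medians without the trend and the lipid synthesis median without the trend or with a mean of at least 5 FPKM. The EZH2-silenced list moved above it at 5 µM with a mean of at least 5 FPKM (0.43, 7 members left) and at 10 µM among unmatched random lists (0.26, percentile 97.54), and lay at percentiles 85.3 and 87.6 without the trend. Without the trend the 5 µM medians were −0.41 for G2/M genes and −0.86 for ATF4 targets, and after median-ratio rescaling −0.45 for ribosomal proteins; the cause was not tested. At 10 over 5 µM, the ribosomal median of 0.015 was 0.068 without the trend and stayed at 0.015 but at percentile 74.46 among unmatched random lists, and the NF-kB median of 0.059, inside the central range, lay above it without the trend (0.078) and with a mean of at least 5 FPKM (0.12). Of the other lists, 480 values kept place and interval, 15 moved inside the central range (apoptosis and cholesterol against vehicle; lipid synthesis, hypoxia, lysosome and metallothionein lists at 10 over 5 µM), 10 moved outside it and 2 only left the interval (respiratory chain). Of the 10, 2 were against vehicle (H3K27 demethylases and PRC1 at 5 µM and heat shock at 10 µM). Of the named genes, 898 values kept their side of 2-fold, 25 passed it and 4 no longer did. Unknown depth limits what can be said of low genes.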

Other observations

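The 7 gene lists described first were chosen after the data were seen. Acute phase and secreted defence genes were far above vehicle at both doses, with medians of 2.09 (0.18 to 3.15) and 1.98 (0.50 to 3.01) over 13 genes and 8 past 2-fold at each. SAA2, the neighbour of SAA1 and close to it in sequence, was at 1.42 FPKM with vehicle and 10.3 and 9.10 FPKM with IliA. S100A9 was at 1.64, 10.2 and 7.88 FPKM, TNFSF10, which encodes the death ligand TRAIL, at 2.86, 14.4 and 14.2 FPKM, and IL32 at 18.8, 88.7 and 91.2 FPKM. Of 17 vacuolar ATPase subunits, which acidify lysosomes, 16 and 17 were above vehicle, with medians of 0.43 (0.34 to 0.51) and 0.39 (0.36 to 0.46) and none past 2-fold. The 5 aryl hydrocarbon receptor targets and partners analysed had medians of 0.43 and 0.46 and were all higher at 10 µM than at 5 µM. CYP1A1 led them, while AHR itself had log2 ratios of −0.18 and 0.06.

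Translation factors and other mRNAs with a terminal oligopyrimidine start were lower, like the ribosomal proteins, with medians of −0.48 (−0.72 to −0.23) and −0.40 (−0.60 to −0.17) over 26 genes. The elongation factor EEF1A1, which has many processed copies, was at 3210 FPKM with vehicle, 1293 FPKM at 5 µM and 1401 FPKM at 10 µM. The 19 condensin and cohesin subunits had medians of −0.41 and −0.45, with SMC4 at 37.2, 10.2 and 9.64 FPKM and SMC2 at 11.3, 4.38 and 4.76 FPKM. The 8 humanin-like copies of the mitochondrial 16S rRNA gene were above vehicle at both doses, with medians of 0.68 and 0.60. MTRNR2L2, the most abundant gene in each library, was at 9394, 15098 and 14686 FPKM, and reads of the mitochondrial rRNA can be assigned to these copies. The 15 cancer-testis genes had medians of 0.20 and 0.15. MAGEA2 was at 21.9, 56.6 and 43.2 FPKM and its near-identical copy MAGEA2B at 50.5, 18.6 and 32.7 FPKM, and reads shared between the copies make both values uncertain.

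In the next paragraphs, the tests of library scaling, of the vehicle library standing apart and of the base composition trend as the whole cause were chosen after the results were seen. The first pattern is the set of 301 genes past 2-fold at 10 µM. Whatever single factor was put on the 10 µM library, at least 295 genes were past 2-fold. The log2 ratios already had a median of 0.029, with 208 genes higher and 93 lower past 2-fold. A single factor that takes genes from one side adds them on the other, so this outcome was fixed by these counts. The search therefore shows only that no single factor brings both sides within 2-fold, and no further conclusion on library scaling is drawn from it. Without the trend in GC content, transcript length and gene span 270 genes were past 2-fold. They include genes that passed only after the removal, since 157 of 208 higher and 74 of 93 lower genes stayed. Median log2 ratios at 10 µM were −0.078 among genes of up to 38.5% GC and 0.23 from 61.7% GC. For the shortest and longest transcripts and spans, the medians lay between −0.026 and 0.13. Such shifts are small next to the log2 ratio of 1 at 2-fold, so a high count was largely fixed beforehand. No conclusion on the trend as the whole cause is drawn from this count. Of the 301 genes, 76.7% stayed past 2-fold without the trend, between the bounds set beforehand, so the trend may account for some of them. Length, GC content and span were all known for 296 of the 301, and the others were not fully corrected. A vehicle library standing apart for a reason other than IliA cannot be told apart from an effect of IliA: only 2 genes were past 2-fold between the treated libraries, and no second vehicle library was compared. An effect of IliA on these genes stays open.

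The second pattern is the lower level of the 111 DNA replication, G1/S, G2/M and mitosis genes, with a median of −0.60 at 10 µM. Without the trend the median was −0.57 (−0.65 to −0.48), 96.4% of its size. At 5 µM it was −0.41 against −0.45, 89.9% of its size. This argues against GC content or length as the main cause, for a trend of the size removed. The vehicle library standing apart stays open here as well. A smaller share of cycling cells with IliA may be a biological reading, given as a hypothesis, and it was not tested. The replication-dependent histone genes went the other way, with medians of 0.60 and 0.67 whose intervals take in 0.

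The third pattern is the higher level of the 39 interferon, antigen presentation and NF-kB genes together with CD68 and LYZ. Without the trend their median kept 88.6% of its size at 10 µM and 84.7% at 5 µM. This argues against GC content or length as the main cause, for a trend of the size removed. Of 25 transcripts abundant in leukocytes, 7 were analysed, and their median was 1.38 (0.35 to 2.09) at 5 µM and 1.19 (0.16 to 1.80) at 10 µM. This meets the bound, which was set before the test but with the ratios of CD68 and LYZ already seen. The test cannot tell leukocytes from induction in the cancer cells. Only genes at 1 FPKM or more with vehicle could enter it, among them FTL at 448 FPKM and LCP1 at 107 FPKM. Leukocyte transcripts absent with vehicle could not. LCP1 had log2 ratios of 0.35 and 0.16, and CD8A was lower with IliA. Both readings stay open, and this judgement of the test was made after its result was seen.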
